A study of Mus musculus with 16 samples.

How the data were processed

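RNA was sequenced from 16 cultures of 5 mouse T-cell acute lymphoblastic leukaemia (T-ALL) cell lines. Per the labels, 4 lines (2883, 2696, 2641 and 2869) came from Mcm2cre/cre mice, in which a Cre insertion lowers expression of the replication helicase subunit Mcm2, and 1 line (7298) came from SCL/LMO1 transgenic mice. Each line was profiled as the parental culture, and 11 derivatives resistant to 1 of 5 drugs were profiled beside them: 3 to cytarabine, 3 to vincristine, 2 to etoposide, 2 to prednisone and 1 to methotrexate. Each culture is 1 library, and no culture was sequenced again. A p-value here therefore rests on the spread between cultures that is left after the model terms given below, 1 of them per line.

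The authors deposited 1 table of FPKM values for 13474 genes. The submitters' processing notes name cutadapt, STAR, Partek and the mm10 build, with no versions; the annotation and the counting method are not given in the sources used here. In the deposited FPKM values the length of each gene is its whole span, end minus start with introns, in all 13474 rows, so FPKM of genes with long introns is low and FPKM should be compared between libraries and not between genes. The values also show a constant of 0.1 read per gene added before scaling. Of 13201 gene symbols found in the GENCODE vM21 annotation, 13080 had the same start and end, and coordinates are given as in the deposited table, on mm10.

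CPM, read counts scaled to the library total, were obtained by multiplying FPKM by gene length, and reads by multiplying CPM by the depth that the steps between low values imply. Depth was 12142000 to 13498000 reads in the 5 parental libraries and 14066000 to 18956000 in the 11 resistant ones, so depth separates these groups completely. Between 0.5 and 200 reads, 70.6% to 75.7% of values per library lay within 0.05 of a whole read, which is too few for a test on counts. Ratios between a derivative and its parental library are given with 95% exact (Clopper-Pearson) binomial intervals on these reads. Where 1 library had 0 reads the ratio is a lower bound against 3 reads per library. Intervals and bounds cover counting error only.

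Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with a mean-variance trend) on log2(FPKM + 1), for 9309 genes with at least 1 FPKM in at least 2 libraries. Fold changes are on this log2(value + pseudocount) scale, which understates changes of low genes. The model had 1 term per cell line and 1 per drug and was fitted to all 16 libraries, with 6 residual degrees of freedom. A second model had a single term for resistance, with 10 residual degrees of freedom. Cytarabine was contrasted with the mean of the other 4 drugs in the first model. P-values are two-sided and were adjusted by the Benjamini-Hochberg method at a threshold of 0.05. Errors are standard errors (SE) of the model. The methotrexate derivative, alone in its group, was described without a test.

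The cell line is the block that pairs a derivative with its parental culture, because the labels name the same line for both. As a check, the deviation of each derivative from the mean of all libraries correlated best with that of its own parental library in 10 of 11 derivatives (own r from -0.01 to 0.76, across genes); the exception was the etoposide-resistant derivative of 2883. Because line 2883 gives 6 of the 16 libraries and pulls that mean toward itself, the correlation of the log2 values themselves was added after this result was seen, and by it the own parental library ranked highest in 11 of 11 derivatives (r from 0.94 to 0.98). No pair of libraries came close to sampling noise (the lowest mean chi-square per gene was 52.2).

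A list of 28 known drug resistance genes and 31 gene lists were fixed before the data were examined. Of the resistance genes, 25 have a row in the table. For a resistance gene, a p adjusted over the list alone covers only the tested genes listed for that drug. These were 4 genes for cytarabine and 5 each for vincristine, etoposide and prednisone. Gene lists with at least 5 tested members, 24 of 31, were tested with camera at a preset correlation of 0.01, and again with an estimated correlation and with fry. Genes named are, for each comparison, up to 10 per direction past the threshold with the same sign in every derivative; where none passed, the 5 per direction with the smallest p, given as not called; the resistance genes of each drug; and up to 4 members of each list past the threshold. Predicted gene models were left out of these choices; those named elsewhere were singled out after their values were seen. Some genes that these rules select are not reported here. Transcripts were counted as lost at 5 FPKM or more in the parental library and 0.1 or less in the derivative, and as gained in the reverse case.

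Alternatives chosen before the data were examined were a fit without the line block, a pseudocount of 0.1, no filter, median-of-ratios scaling, quantile normalization, no trend, line 7298 left out, only the libraries of 1 drug and their parental partners, each library left out in turn, and other limits for lost and gained transcripts. A fit on log2(CPM + 1) and limits in reads were added after seeing the data. Simulated data held 50 changed genes per size. In them the cytarabine test recovered 76% of changes of 1 on the log2 scale and 98% of changes of 2. For prednisone these were 62% and 96%. The simulated changes were equal in every derivative of a drug, with normal noise. They were placed only in genes with a mean above 2 on that scale. The percentages therefore do not hold for changes that differ between derivatives or for genes at lower values. Neighbouring genes were examined on log2(CPM + 1) of protein-coding genes with a mean of at least 3 CPM, in windows of 5 genes, with limits from 1000 shuffled gene orders. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.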

Results

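The libraries covered 5 T-ALL lines in the parental state and 11 derivatives resistant to a chemotherapy drug, with the series centred on resistance to cytarabine. Line 2883 contributed a derivative for each of the 5 drugs, lines 2696 and 2869 contributed 2 each, and lines 2641 and 7298 contributed 1 each. Mcm2 was measured at 20.9 and 29.2 FPKM in the 2 libraries of line 7298 and at 3.53 to 12.2 FPKM in the 14 libraries of the Mcm2cre/cre lines. Lmo1, the oncogene of the transgene of line 7298, was at 7.37 FPKM in its parental and 6.07 FPKM in its cytarabine-resistant library, and at most 0.000225 FPKM in the other 14 libraries. Tal1 (SCL) was at most 0.00406 FPKM in line 7298 and at most 0.375 FPKM in the others. Mitochondrial transcripts took 2.31% to 5.53% of reads per library.

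Cytarabine resistance was compared with the parental state in lines 7298, 2883 and 2869. Dck, the kinase that makes the first phosphorylation of cytarabine (chromosome 5, 88764996 to 88783281), was lower in each of the 3 derivatives. In line 7298 it went from 1304 reads to 0, at least 609-fold lower; in line 2883 the derivative had 0.216 of the parental level (95% interval 0.197 to 0.237), and in line 2869 it had 0.578 (0.541 to 0.618). Its log2 fold change was -1.61 ± 0.31 (SE, n = 3 derivatives). The limma adjusted p of Dck was 0.00202 over the 4 tested genes of the cytarabine list alone, and 0.404 over all genes tested. In the 8 derivatives resistant to other drugs Dck was between 0.614 and 1.69 of the parental level. Of the other resistance genes, Rrm2, a ribonucleotide reductase subunit, had a log2 fold change of 0.65 ± 0.26 (limma adjusted p = 0.0693 over the list alone). The nucleoside transporter Slc29a1 was at -0.04 ± 0.21 and Rrm1 at 0.04 ± 0.17. Nt5c2, a nucleotidase below the expression filter, was at 1.8 of the parental level in line 2883 and at 1.14 and 1.19 in lines 7298 and 2869.

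No gene passed the threshold over all genes for cytarabine. Limma called 0 of 9309, with 1037 at an unadjusted p under 0.05 (551 higher and 486 lower) and a smallest adjusted p of 0.404. On log2(CPM + 1) limma called 0 with 1249 at an unadjusted p under 0.05. The smallest p among higher genes belonged to Rasgrp2 (log2 fold change 0.74 ± 0.13), E2f8 (0.84 ± 0.15), Patz1 (0.95 ± 0.18), Dvl2 (0.78 ± 0.15) and Zfp574 (0.46 ± 0.09), each higher in 3 of 3 derivatives. After Dck, those among lower genes were Rbis (-0.50 ± 0.10), Med21 (-0.50 ± 0.10), Commd3 (-0.55 ± 0.12) and Pgk1-rs7 (-1.56 ± 0.34), lower in 3 of 3; Pgk1-rs7 is a copy of Pgk1 and may share its reads.

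As a list, 54 cytosolic ribosomal protein genes had a median log2 fold change of -0.32 in the cytarabine derivatives, with 1 of 54 higher (camera adjusted p = 1.12e-15; adjusted p = 0.798 with an estimated correlation). Rps27 was at -0.48 ± 0.11 and Rpsa at -0.67 ± 0.18. The 35 tested genes of glycolysis and the hypoxia response had a median of -0.59, with 3 of 35 higher (camera adjusted p = 7.63e-11; adjusted p = 0.863 with an estimated correlation). The glycolytic enzymes Pgk1 (-1.43 ± 0.32), Ldha (-0.86 ± 0.22) and Eno1 (-1.56 ± 0.41), and Higd1a (-0.77 ± 0.20), were among the 5 members that fell when adjusted over the list alone. The other 22 lists tested did not pass for cytarabine.

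**Figure D1:**
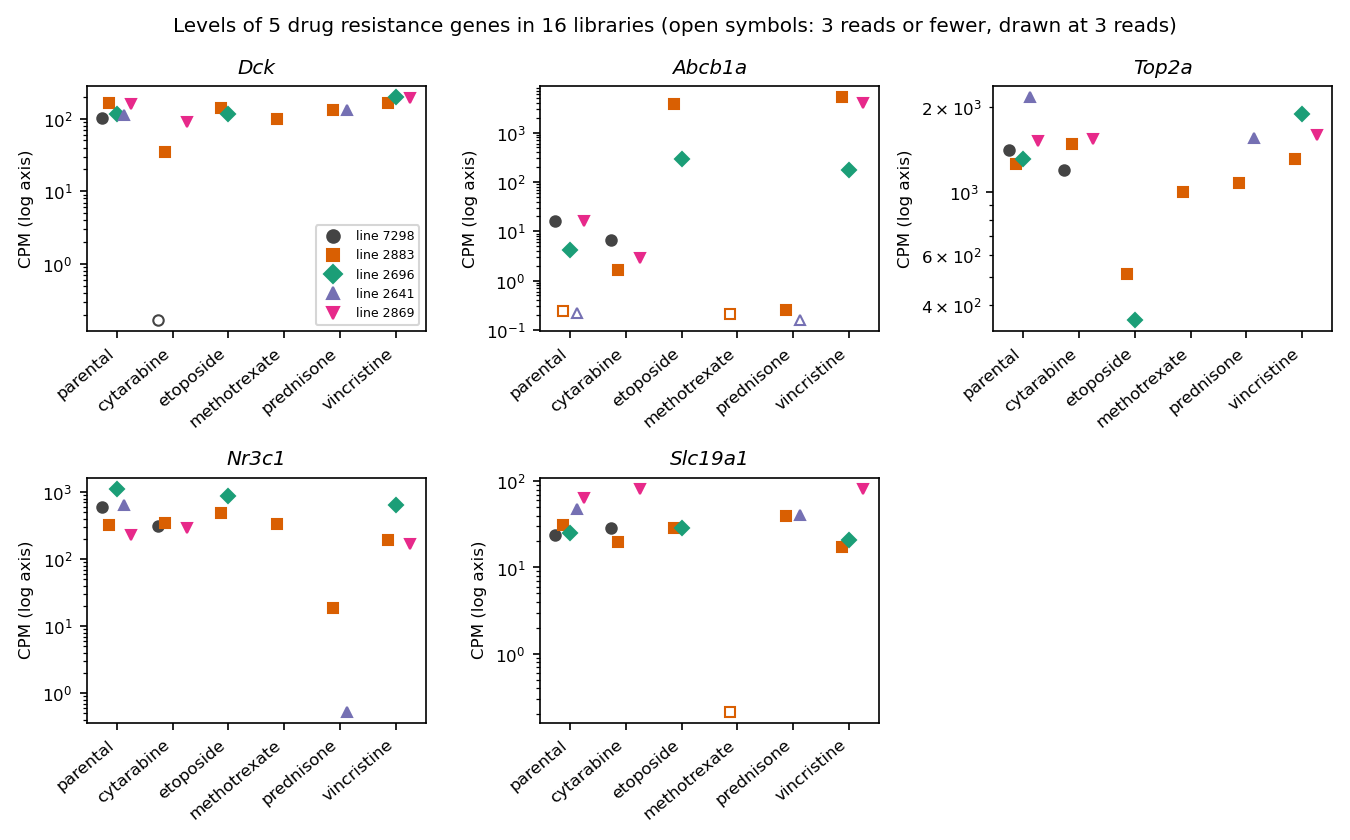
CPM (log axes) of Dck, Abcb1a, Top2a, Nr3c1 and Slc19a1 in each of the 16 libraries, by drug, with 1 symbol per line; open symbols are libraries with 3 reads or fewer, drawn at 3 reads. Dck was at 0 reads in the cytarabine-resistant derivative of 7298, Nr3c1 at 10 reads in the prednisone-resistant derivative of 2641, and Slc19a1 at 0 reads in the methotrexate-resistant derivative of 2883.

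Vincristine resistance was compared with the parental state in lines 2883, 2696 and 2869. Abcb1a, which encodes the drug efflux pump P-glycoprotein (chromosome 5, 8660077 to 8748575), rose in 3 of 3 derivatives: from 0 to 76461 reads in line 2883 (at least 21196-fold higher), 248-fold in line 2869 (95% interval 217 to 285) and 41.7-fold in line 2696 (32.0 to 55.4). Its log2 fold change was 4.39 ± 0.66 (limma adjusted p = 0.000395 adjusted over the list alone, and 0.113 over all genes). Its paralog Abcb1b was at 2.17 ± 0.62 (0.0165 over the list alone), with 116-fold and 17.2-fold in lines 2883 and 2869 and 1.49-fold in line 2696; reads shared by the 2 paralogs could be assigned to either. The neuronal tubulin Tubb3 was at -0.70 ± 0.35, Tubb2b at -0.34 ± 0.48 and Tubb5 at 0.21 ± 0.12, none called.

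Over all genes limma called 0 for vincristine, with 1289 at an unadjusted p under 0.05 (553 higher and 736 lower); on log2(CPM + 1) it called 0 with 1727. Beside Abcb1a, the smallest p among higher genes belonged to Nfe2l1 (0.70 ± 0.11), a regulator of proteasome genes, Lgals3bp (1.07 ± 0.18), Acsf2 (0.82 ± 0.15) and Mia2 (0.78 ± 0.15). Among lower genes it belonged to Mir17hg (-1.34 ± 0.20), the host of a microRNA cluster, the transcription factor Klf6 (-1.89 ± 0.30), Phtf1os (-0.93 ± 0.15), Rbis (-0.58 ± 0.10) and Pgk1-rs7 (-2.02 ± 0.34). The glycolysis and hypoxia list had a median of -0.83 with 2 of 35 higher (camera adjusted p = 5.92e-12; adjusted p = 0.807 with an estimated correlation). In this list 14 members passed when adjusted over the list alone, among them Ldha (-1.26 ± 0.22), Pgk1 (-1.81 ± 0.32), Eno1 (-1.99 ± 0.41) and Tpi1 (-1.62 ± 0.35). Ribosomal protein genes had a median of -0.25 (camera adjusted p = 1.72e-06; adjusted p = 0.807 with an estimated correlation), with Rps7 at -0.81 ± 0.17. Cholesterol biosynthesis genes had a median of -0.18 (camera adjusted p = 0.00646; adjusted p = 0.817 with an estimated correlation), with Msmo1 at -0.82 ± 0.18. The integrated stress response list had a median of 0.27 with 27 of 31 higher (camera adjusted p = 0.000111; adjusted p = 0.807 with an estimated correlation), although Ddit4 was at -2.08 ± 0.84. The Notch list had a median of 0.18 (camera adjusted p = 0.00646; adjusted p = 0.807 with an estimated correlation), with Dtx1 at 1.12 ± 0.27 and Notch1 at 1.29 ± 0.34. Without the line block limma called 3 genes (Pgk1-rs7, Pgk1 and the predicted gene Gm5537), and without the parental library of 2696 it called 9, with Abcb1a at an adjusted p of 1.33e-05 (1.33e-05 to 0.554 over the alternatives). Leaving out the parental library of 7298 gave 2 calls (Rab11fip4 and Gm42979), that of 2883 gave 2 (Klf6 and Gm37829) and the vincristine derivative of 2883 gave 1 (Gm49013); genes in these counts were chosen after their values were seen.

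Etoposide resistance was compared with the parental state in lines 2883 and 2696. Top2a, the topoisomerase that etoposide traps on DNA (chromosome 11), was at 0.412 of the parental level in line 2883 (95% interval 0.401 to 0.424) and 0.271 in line 2696 (0.263 to 0.279). Its log2 fold change was -1.61 ± 0.22 (n = 2 derivatives; limma adjusted p = 0.000174 adjusted over the list alone, and 0.126 over all genes). Abcb1a rose from 0 to 53577 reads in line 2883 (at least 15206-fold higher) and 67.0-fold in line 2696 (51.5 to 88.8; log2 fold change 4.17 ± 0.77, adjusted p = 0.000965 over the list alone and 0.299 over all genes). Abcb1b was 203-fold higher in line 2883 and went from 1090 to 810 reads in line 2696 (95% interval of the ratio 0.518 to 0.623). Top2b was at -0.17 ± 0.17 and Tdp2, which removes trapped topoisomerase from DNA, at -0.32 ± 0.22. Abcc1, below the filter, was 6.87-fold and 1.09-fold higher.

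Limma called 0 genes over all genes for etoposide, with 827 at an unadjusted p under 0.05 (334 higher and 493 lower); on log2(CPM + 1) it called 0 with 1151. The smallest p belonged, after Top2a, to Mfsd13a (0.95 ± 0.14), Mir17hg (-1.60 ± 0.24), Aacs (1.04 ± 0.16), the sterol enzyme Lss (1.01 ± 0.15) and Limk1 (0.73 ± 0.11). They were followed by Glrx (-0.95 ± 0.15), Commd3 (-0.88 ± 0.14) and Ptbp3 (-0.99 ± 0.17), each with the same sign in 2 of 2 derivatives. Cholesterol biosynthesis genes had a median of 0.48 with 21 of 23 higher (camera adjusted p = 6.50e-11; adjusted p = 0.546 with an estimated correlation), and Lss, Mvd (0.92 ± 0.20), Mvk (0.61 ± 0.14) and Msmo1 (0.76 ± 0.21) rose when adjusted over the list alone. Mitosis and proliferation genes had a median of -0.32 with 4 of 32 higher (camera adjusted p = 2.81e-07; adjusted p = 0.546 with an estimated correlation), with Cdk1 at -0.52 ± 0.15, Birc5 at -0.64 ± 0.20 and Ccna2 at -0.55 ± 0.17 beside Top2a. The glycolysis and hypoxia list had a median of 0.30 (camera adjusted p = 0.000559; adjusted p = 0.873 with an estimated correlation), opposite in sign to vincristine and cytarabine, with Hk1 at 0.71 ± 0.26. The integrated stress response list had a median of 0.32 (camera adjusted p = 0.000273; adjusted p = 0.873 with an estimated correlation), with Sesn2 at 0.67 ± 0.26. Leaving out the parental library of 2696, the derivative of 2883 or that of 2696 gave 3, 3 and 5 called genes. The first held Abcb1a at an adjusted p of 5.16e-05 (5.16e-05 to 1.00 over the alternatives), the second Gzmb, Trgv3 and Kcnab2, and the last Aacs and Sri among others, chosen after their values were seen.

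Prednisone resistance was compared with the parental state in lines 2883 and 2641. Nr3c1, the glucocorticoid receptor (chromosome 18, 39410545 to 39519421), fell to 0.0566 of the parental level in line 2883 (95% interval 0.0504 to 0.0635) and from 8484 to 10 reads in line 2641, a ratio of 0.000826 (0.000396 to 0.00152). Lmcd1, a LIM domain cofactor (chromosome 6), rose 48.3-fold in line 2883 (34.7 to 69.6) and 255-fold in line 2641 (99.5 to 939). These were the 2 genes that limma called, Nr3c1 with a log2 fold change of -2.31 ± 0.26 (adjusted p = 0.0346 over all genes, 3.72e-05 adjusted over the list alone) and Lmcd1 with 1.46 ± 0.14 (adjusted p = 0.0193). In all, 853 genes had an unadjusted p under 0.05. Bcl2l11, a death gene induced by glucocorticoids, was at 0.02 ± 0.19, Fkbp5, a target of the receptor, at 0.16 ± 0.25, and Il7r at 0.08 ± 0.38, with 0.498 of the parental level in line 2883 and 2.81 in line 2641.

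Neither gene was called without the line block (adjusted p = 0.771 for Nr3c1 and 0.968 for Lmcd1) or on log2(CPM + 1) (0.108 and 0.0606), and 0 genes were called without the parental library of 7298, that of 2696 or the prednisone derivative of 2883. Without a filter or with median-of-ratios scaling Lmcd1 alone was called, and without the parental or prednisone-resistant library of 2641 Nr3c1 was at an adjusted p of 0.126 and 0.129. Over the alternatives the adjusted p ranged from 0.0167 to 0.773 for Nr3c1 and from 0.0132 to 0.968 for Lmcd1. Camera called 4 lists, each at an adjusted p = 0.929 with an estimated correlation, and fry called 0. Ribosomal protein genes had a median of -0.37 with 5 of 54 higher (camera adjusted p = 1.36e-11), among them Rpl7 (-0.71 ± 0.18) and Rpl22 (-1.07 ± 0.34). Cholesterol biosynthesis genes had a median of 0.37 with 21 of 23 higher (camera adjusted p = 4.02e-05), among them Lss (0.62 ± 0.15). The integrated stress response list had a median of -0.15 (camera adjusted p = 0.0185), with Cebpb at -1.11 ± 0.31 and Trib3 at -1.23 ± 0.45. Glycolysis and hypoxia genes had a median of -0.35 (camera adjusted p = 0.0401), with Aldoc at 1.43 ± 0.54 and Ldha at -0.59 ± 0.26.

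The methotrexate-resistant derivative was a single culture of line 2883, compared with its parental library without a test. Slc19a1, the reduced folate carrier that takes up methotrexate (chromosome 10, 77032241 to 77061002), went from 377 reads to 0, at least 146-fold lower. Thymidylate synthase (Tyms) was at 0.496 of the parental level, Fpgs at 1.24 and Ggh at 2.57. Inhbb was 125-fold, Ifitm2 37.1-fold and Lgals1 8.18-fold higher. Xist went from 27116 to 5 reads, Bex1 from 517 to 0 (at least 200-fold lower) and Marcks to 0.0866 of the parental level. The other 7 lowest genes were T cell receptor beta V genes. Some of these changes were not particular to methotrexate. Bex1 was also lost in the cytarabine (517 to 1 reads) and prednisone (517 to 0) derivatives of 2883. Inhbb was also 72.7-fold higher in the prednisone derivative of 2883. All derivatives of 2883 share its parental library. Among 3396 genes at 5 FPKM or more in either library, 59 were higher and 87 lower by at least 1 on the log2 scale.

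**Figure D2:**
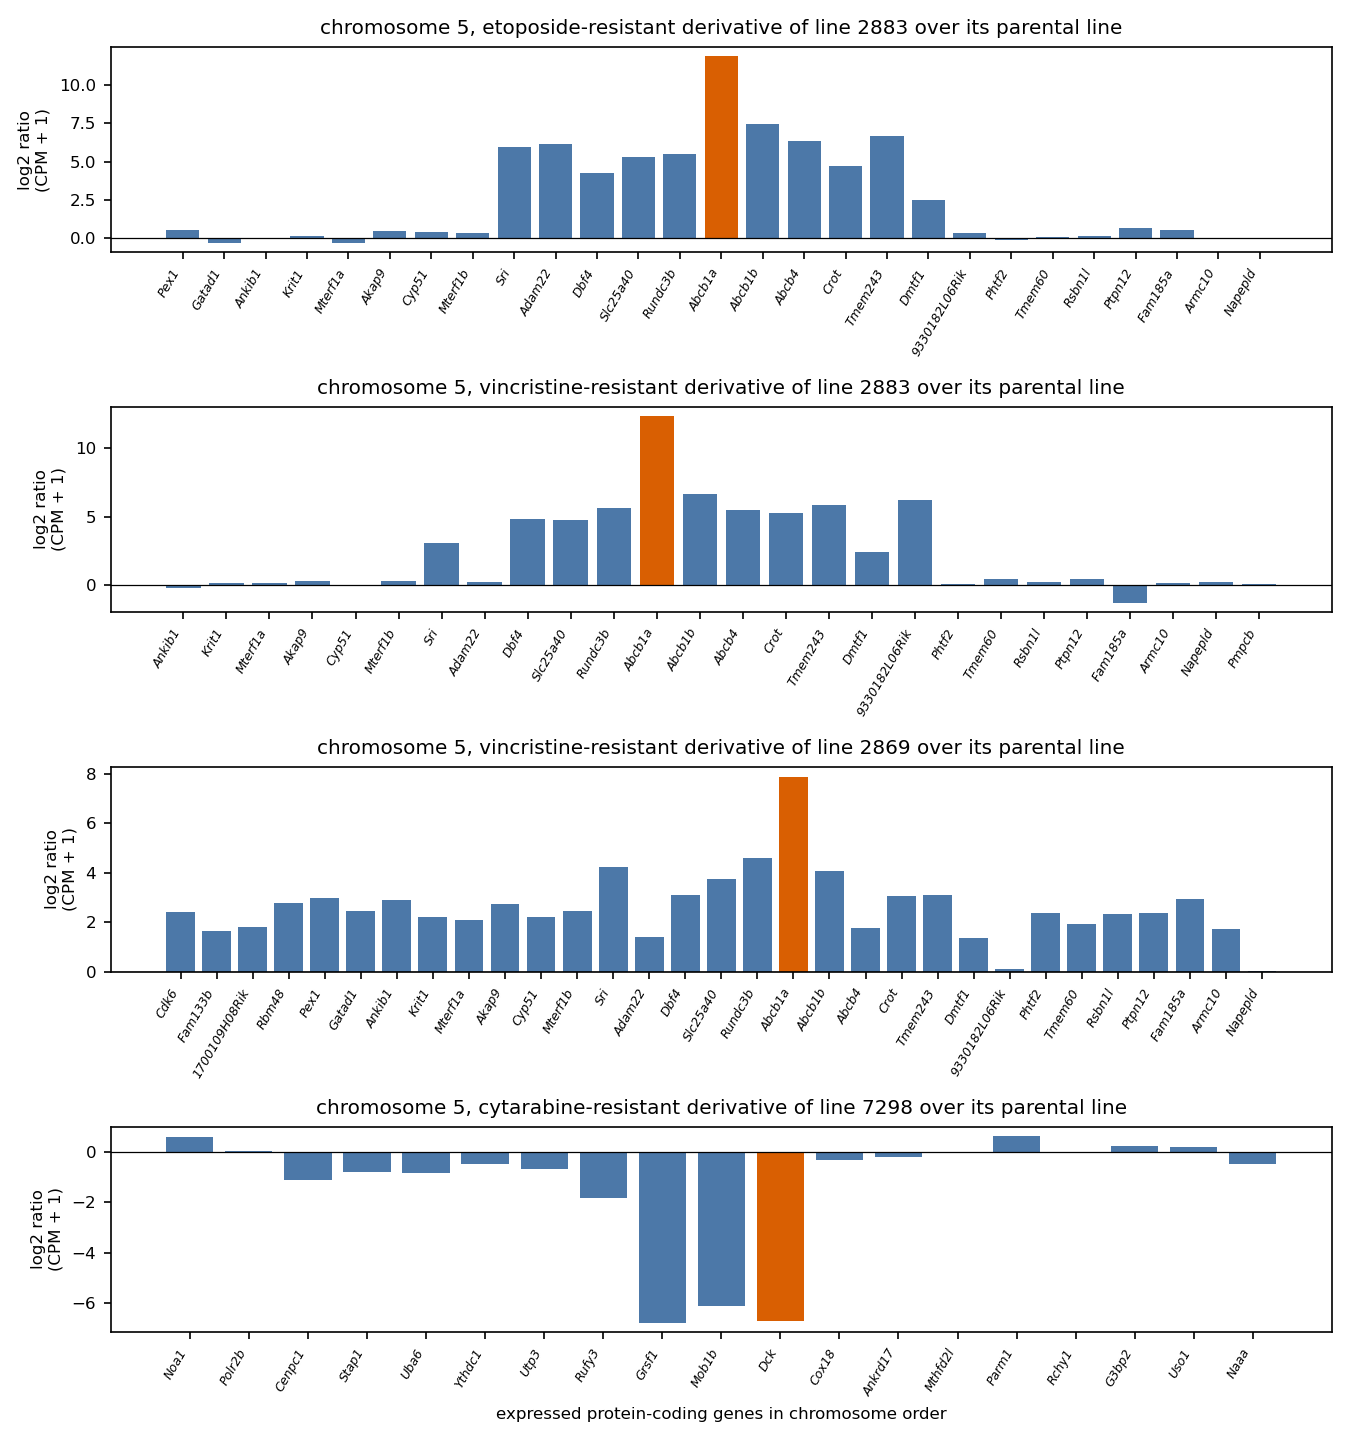
Log2 ratio of CPM + 1 of a derivative over its parental library for expressed protein-coding genes in chromosome order, around Abcb1a and Dck (orange). The raised runs held 11, 10 and 23 genes around Abcb1a (the last interrupted at a gene with 1 read), and the lowered run 3 genes around Dck.

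The 11 resistant libraries together were compared with the 5 parental ones for changes shared over drugs. Limma called 0 genes, with 907 at an unadjusted p under 0.05 (354 higher and 553 lower) and a smallest adjusted p of 0.0728; on log2(CPM + 1) it called 0 with 1105. Rbis (-0.50 ± 0.09, adjusted p = 0.176), Crbn (-0.43 ± 0.09), a ubiquitin ligase receptor, Eif3m (-0.44 ± 0.09), Med21 (-0.38 ± 0.08) and Lpar6 (-0.75 ± 0.16) were lower in 11 of 11 derivatives. Gpaa1 (0.51 ± 0.12), Dvl2 (0.52 ± 0.13), Brd1 (0.28 ± 0.07) and the pseudogene Eif1-ps2 (0.45 ± 0.11) were higher in 11 of 11, and Ipo4 (0.45 ± 0.11) was higher in 10. Derivatives of a line share its parental library, so the 11 signs are not independent. Camera called 4 lists, each at an adjusted p = 0.978 with an estimated correlation, and fry called 0. Ribosomal protein genes had a median of -0.24 with 1 of 54 higher (camera adjusted p = 2.20e-10), and glycolysis and hypoxia genes a median of -0.45 (3.27e-05), with Pgk1 at -1.06 ± 0.39. The Notch list had a median of 0.17 (0.00871), with Notch1 at 0.87 ± 0.27, and cholesterol biosynthesis a median of 0.17 (0.0235). Depth was higher in each resistant library than in any parental one, so depth and resistance cannot be separated for shifts of this size; without either library of 7298, 2 predicted genes (Gm38057 and Gm42979, chosen after their values were seen) were called.

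Cytarabine resistance was contrasted with resistance to the other 4 drugs. Limma called 2 genes, among them Zcchc9 (log2 difference -1.26 ± 0.14, adjusted p of 0.0483), with 765 at an unadjusted p under 0.05. Zcchc9 was 54.3-fold higher in the methotrexate derivative than in its parental library, and at 1.09, 1.07 and 0.996 of the parental level in the 3 cytarabine derivatives. Its difference thus comes from that methotrexate library, without which the contrast could not be estimated, and it is named although it does not share a sign with cytarabine. On log2(CPM + 1) limma called 0, with 1084 at an unadjusted p under 0.05; without either library of 7298 it called 1 gene, Cd8b1, without the parental library of 2883 it called Ripk3, and without that of 2696 Abcb1a and Gm42686, chosen after their values were seen. Cd8b1 (1.42 ± 0.24), Trim65 (0.63 ± 0.11), Zfp526 (0.79 ± 0.14), E2f8 (0.82 ± 0.16) and Tspan6 (0.75 ± 0.15) had the smallest p among genes higher with cytarabine. Against its own parental library, Cd8b1 was higher in 2 of the 3 cytarabine derivatives and lower in 1. Trim65, Zfp526, E2f8 and Tspan6 were higher in 3 of 3. Serinc5 (-0.99 ± 0.14), Cd151 (-0.85 ± 0.16) and Lmcd1 (-0.60 ± 0.12) had the smallest among lower genes that were not called. Of these, Cd151 was below the parental level in the 3 cytarabine derivatives (0.663, 0.729 and 0.681). Serinc5 was at 0.966, 1.74 and 1.57 of it and 50.8-fold higher with methotrexate, and Lmcd1 was at 1.14, 4.86 and 13.5 and rose further with prednisone (48.3-fold and 255-fold).

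By list, camera called 7 for this contrast; each of them had an adjusted p = 0.550 with an estimated correlation, and fry called 0. Mitosis and proliferation genes were higher with cytarabine than with the other drugs (median 0.29, 29 of 32 higher, camera adjusted p = 8.18e-08). Of these, Mki67 (0.70 ± 0.16), Cdc20 (0.57 ± 0.14), Foxm1 (0.51 ± 0.14) and Prc1 (0.45 ± 0.13) passed when adjusted over the list alone. Of the 7 lists, only ribosomal proteins and glycolysis and hypoxia also passed for cytarabine against the parental state. The mitosis list did not, and it was lower with etoposide, so its contrast does not show a rise above the parental level. T cell receptor and thymocyte identity genes had a median of 0.29 (camera adjusted p = 0.00789), with Cd8b1 and Cd8a (1.80 ± 0.46) among the 3 members passing over the list alone. Homologous recombination and Fanconi anaemia genes (median 0.15, 0.00466), with Slx4 at 0.49 ± 0.12, and replication licensing genes (median 0.13, 0.0252), with Ticrr at 0.58 ± 0.12 and Mcm2 at 0.44 ± 0.15, were also higher. Ribosomal protein genes (median -0.20, 3.33e-11), with Rps27 at -0.42 ± 0.11, glycolysis and hypoxia (median -0.45, 9.15e-10), with Higd1a at -0.62 ± 0.20, and mitochondrial transcripts (median -0.14, 0.0252), with mt-Rnr2 at -0.84 ± 0.35, were lower.

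Fold changes of different drugs were correlated across 9309 genes, which are not independent replicates, and drugs share parental libraries. Etoposide and vincristine had r = 0.44 and a covariance of 0.0504, where 100 simulations of unchanged groups against the same parental libraries gave a mean r of 0.38 and a covariance of 0.0208. Cytarabine and vincristine had r = 0.37, within the simulated range (mean 0.35, highest 0.39), and a covariance of 0.0372 against 0.0160. Cytarabine and prednisone had r = 0.32 (simulated mean 0.21, highest 0.26) and a covariance of 0.0310 against 0.0115. By r, methotrexate lay below the simulated mean with cytarabine (0.04, simulated 0.25), etoposide (0.05, 0.27), vincristine (0.06, 0.27) and prednisone (0.18, 0.25). Etoposide with prednisone did so too (0.13, 0.23). By covariance, methotrexate was below it with cytarabine (0.00477 against 0.0175), etoposide (0.00663 against 0.0223) and vincristine (0.00749 against 0.0191). With prednisone, the covariance was above it for methotrexate (0.0239 against 0.0205) and close to it for etoposide (0.0148 against 0.0150). The parental libraries could not be split within lines, so part of any excess may come from them.

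Summed over the 11 derivatives there were 121 losses or gains of a transcript relative to the parental library, 80 losses and 41 gains. Each derivative had from 1 to 13 losses and from 0 to 10 gains. A transcript lost or gained in several derivatives counts in each of them, so the number of distinct transcripts is smaller. Grsf1 was lost beside Dck in the cytarabine derivative of 7298, from 1375 reads to 0. Xist, the RNA that coats the inactive X chromosome, was lost in 4 derivatives of 4 lines (methotrexate 2883, prednisone 2641, vincristine 2696 and vincristine 2869), with 1 to 25 reads left of 2675 to 47417. Trbv20 and Trbv17 were lost in all 5 derivatives of 2883, and Trbv19, at 1280 reads in the parental library, was at 0 in 4 of them. The T cell receptor gamma constant gene Trgc2 went from 2783 to 4 reads in the cytarabine derivative of 2869, and Trgc1 from 0 to 765 in that of 2883. Barx1 appeared in the vincristine derivative of 2883 (0 to 2726 reads), Gnas in the cytarabine derivative of 2869 (21 to 6913) and Fosb in the prednisone derivative of 2641 (1 to 1417). For marker lists of other cell types, the highest FPKM of each list is given, although FPKM is not comparable between genes here. The highest were Gzma (NK and cytotoxic) at 218 in parental 2641 and Cd24a (B cell), also made by thymocytes, at 125 in parental 2869. Pdgfrb (stromal) reached 10.8 in vincristine 2883 and Cldn4 (thymic epithelial) 9.08 in parental 2641. Epor (erythroid and megakaryocyte) reached 3.17 in prednisone 2883 and Cd68 (myeloid) 2.19 in cytarabine 2869.

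The T cell receptor beta V genes, of which a T cell clone commonly uses 1, differed between parental 2883 and its derivatives. In the parental library Trbv19 took 50.1% of the V gene reads and 10 V genes took at least 1% each. In the derivatives of 2883 the leading gene was Trbv12-1 with cytarabine (91.0%), Trbv12-2 with etoposide (99.2%) and vincristine (93.9%), and Trbv31 with methotrexate (91.9%) and prednisone (68.0%). In lines 7298, 2696, 2641 and 2869 the leading gene of the parental library, at 68.3% to 69.3% of V gene reads, also led in each derivative. These genes were singled out after their values were seen, and V genes resemble each other, so reads may be split between them.

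**Figure D3:**
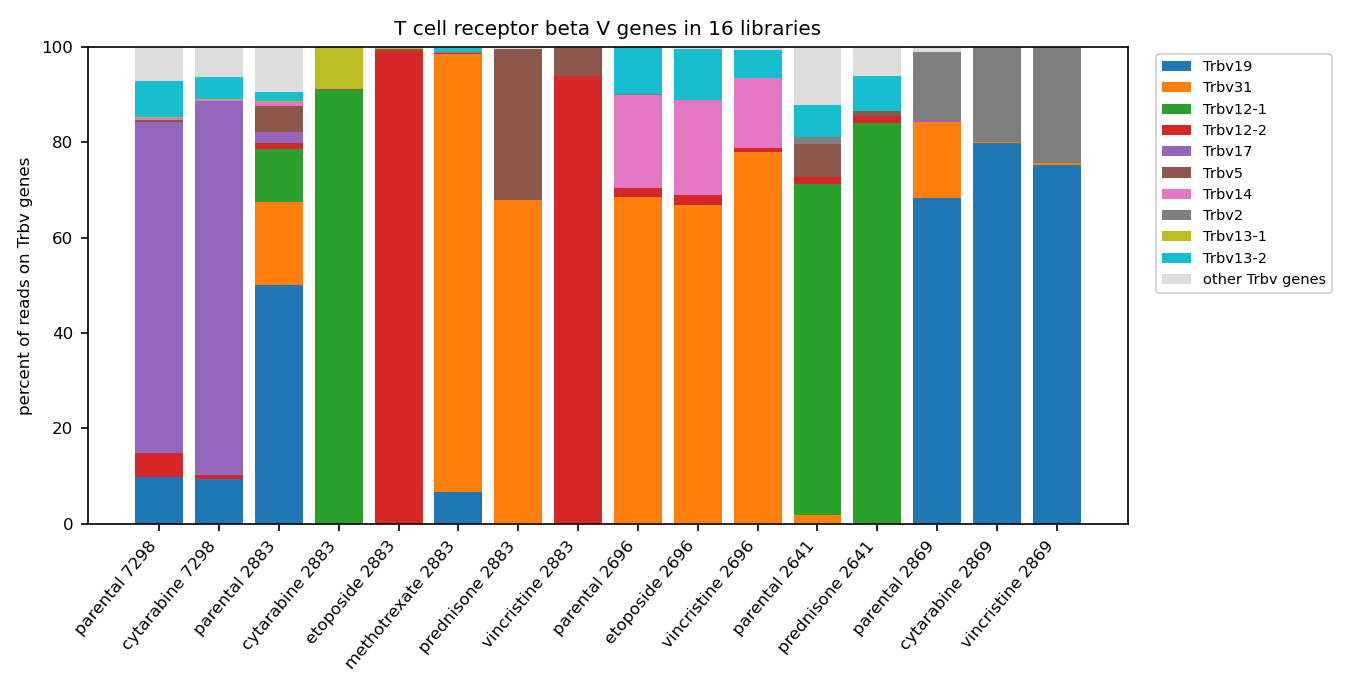
Percent of T cell receptor beta V gene reads taken by each V gene (stacked bars) in each of the 16 libraries. Parental 2883 is led by Trbv19 at 50.1%, and its 5 derivatives by Trbv12-1, Trbv12-2 or Trbv31.

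Some derivatives differed from their parental library along whole chromosomes, which was examined after the values were seen. In the vincristine derivative of 2883 the median log2 ratio on chromosome 8 was -0.70, with 90.8% of 556 genes lower, where random gene sets of that size gave -0.06 to 0.06. In the vincristine derivative of 2696 it was 0.54 on chromosome 11 and 0.42 on chromosome 16, and in the etoposide derivative of that line 0.39 on chromosome 16. In the vincristine derivative of 2869 it was 0.39 on chromosome 5, 0.36 on chromosome 9, 0.40 on chromosome 11 and 0.40 on chromosome 15. Chromosome 13 was lower in all 5 derivatives of 2883, which share 1 parental library: -0.46 with cytarabine, -0.36 with etoposide, -0.39 with prednisone, -0.23 with vincristine and -0.15 with methotrexate. It was also below the random range in the vincristine (-0.20) and cytarabine (-0.09) derivatives of 2869 and the etoposide (-0.09) and vincristine (-0.08) derivatives of 2696. In these derivatives chromosome 13 was not alone below the random range. In line 2869 chromosomes 12 (-0.18) and 18 (-0.17) were also below it with vincristine, and chromosome 3 (-0.08) with cytarabine. In line 2696 chromosome 9 (-0.08) was also below it with etoposide, and chromosome 3 (-0.13) with vincristine.

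**Figure D4:**
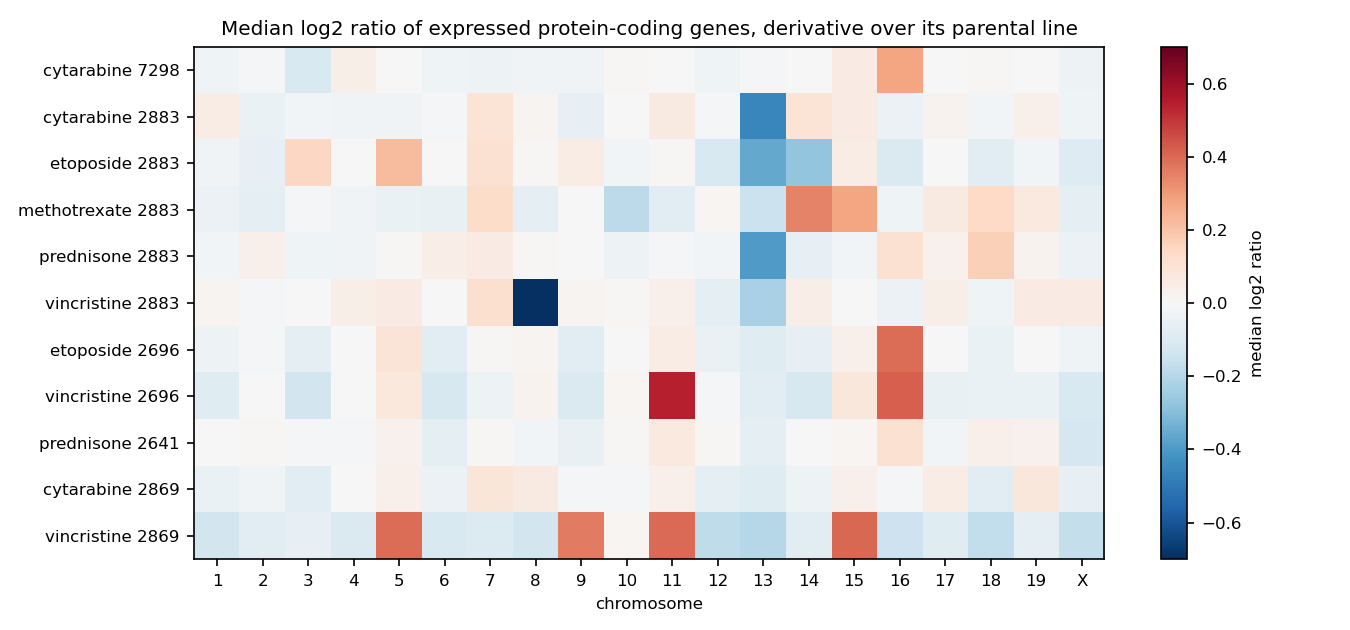
Median log2 ratio of CPM + 1 of each derivative over its parental library (colour) for expressed protein-coding genes, by chromosome. The lowest value is -0.70 for chromosome 8 in the vincristine-resistant derivative of 2883.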

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

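The tests of explanations and the counts of other splits in this part were chosen after the results were seen; the rule for values far from the others was set before. Of 69 values tested in the 5 parental libraries, 7 lay far from the other 4, where chance gives about 3.5.

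Genes around Abcb1a were raised in 3 derivatives, with runs of 11 genes (etoposide 2883), 10 genes (vincristine 2883) and 23 genes (vincristine 2869), against at most 6 in shuffled orders. In vincristine 2869 the run ends at 9330182L06Rik (0 and 1 reads), and genes beyond it were raised as well (Phtf2 2.37, Fam185a 2.94, Psmc2 2.44), so the raised region is longer than the run. As a reason for the raised runs, reads shared between Abcb1a, Abcb1b and Abcb4 are argued against by the other genes of the blocks. Their lowest median log2 CPM ratio was 2.60. These medians leave out Abcb1b and Abcb4, for which shared reads stay open. The shortest run of 10 is consistent with gain of a segment in these 3 derivatives. In the derivatives of 2696 the run at a log2 ratio of 1 or more was 1 gene, Abcb1a itself. In the vincristine derivative of 2696 each expressed coding gene from Sri (1.14) to 9330182L06Rik (1.96) was nonetheless higher, the least being Adam22 (0.29), while Mterf1b and Phtf2 beside them were at -0.10 and 0.18. Some genes farther out were as high (Rbm48 1.25, Cdk6 0.99, Ankib1 0.99), so a smaller gain, limited to the segment or not, stays open there. In the etoposide derivative of 2696 the genes beside Abcb1a went both ways (Rundc3b 0.81, Abcb1b -0.80). Abcb1a rose above its neighbours in every block (log2 ratio 11.87, 12.35 and 7.89), which a uniform gain leaves open.

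Parental 2883 held several T cell receptor beta V genes and its derivatives few. Cells of the other lines in the parental library would bring their markers, and the highest share any marker allowed was 0.449%, against 3.89% to 28.9% needed. Mislabelled derivatives are argued against by Cdkn2a, at 108 CPM or more in the 2883 derivatives and at most 1.14 CPM in libraries of other lines. Subclones present in the parental line predict that the leading V gene of each derivative is already there, above its level in lines that it does not lead. In parental 2883 Trbv12-1 took 11.0% of V gene reads (at most 0.043% in such parental libraries) and Trbv31 17.4% (at most 16.1%). Trbv12-2 took 1.25% (32 reads) against up to 5.10%, a difference of -3.85. Outgrowth of subclones therefore stays open for the derivatives led by Trbv12-2 or Trbv31, since such reads are found in other lines too.

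Parental 7298 was the highest of the parental libraries for Mcm2 (20.9 FPKM, next 7.46), Lmo1 (7.37 FPKM, next 0.000225), Tubb5 (361 FPKM, next 314) and Lss (13.5 FPKM, next 5.05). Parental 2696 was the highest for Bcl2l11 (2.37 FPKM, next 1.11) and Lmcd1 (3.90 FPKM, next 0.325), and parental 2883 the lowest for Pgk1-rs7 (366 FPKM, next 681). Zcchc9 (-1.26) passed limma's test of cytarabine resistance against the other drugs, but the difference comes from the methotrexate library (54.3-fold over its parental library). In the cytarabine derivatives Zcchc9 was at 1.09, 1.07 and 0.996 of the parental level, and without the methotrexate library the contrast could not be estimated.

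Where the real split called 0 genes, any split that could be fitted called as many, so the number of calls decides nothing: 56 of 56 splits for cytarabine (highest other 4), 56 of 56 for vincristine (highest other 16) and 99 of 100 drawn from 4368 for all resistant libraries (highest other 7; 1 split could not be fitted). For cytarabine, 3 of 56 splits had as many as its 1037 genes at an unadjusted p under 0.05 (highest other 1447), so chance is not excluded. For vincristine the real split, with 1289, was the 1 of 56 that reached that number (highest other 1136), but most of the others part fewer pairs of a line, and the 7 that part as many are too few for a share under 0.05. For all resistant libraries, 10 of 100 had as many as 907 at an unadjusted p under 0.05 (highest other 1249). For cytarabine against the other drugs, 58 of 100 splits drawn from 165 called at least 2 genes (highest other 24), and 21 of 100 had as many as 765 at an unadjusted p under 0.05 (highest other 1156), so chance is not excluded in either comparison. Splits that called several times the real number point to structure among the samples, such as the lines. Among other splits that parted as many pairs of a line, the highest number at an unadjusted p under 0.05 was 884 for cytarabine (7 splits), 836 for vincristine (7), 853 for all resistant (14) and 902 for the contrast (23, of which 5 reached the real number).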

How the results depend on the processing

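The fit on log2(CPM + 1) and the limits in reads were chosen after seeing the data; the other alternatives were set before. Cytarabine kept 0 called genes under each alternative run. Without the replicate block that pairs each derivative with its parental line, limma called 3 genes for vincristine and 0 for prednisone, the called drug resistance genes went from 1 to 0, and no other count of calls moved by over 1.5 times. Leaving out line 7298 gave 2 for vincristine, 0 for prednisone, 2 for all resistant, 1 for the contrast of cytarabine with the other drugs and 0 drug resistance genes. For prednisone, no filter gave 1, median-of-ratios scaling 1, log2(CPM + 1) 0 and only the drug and its partners 0; each of these gave 0 drug resistance genes over all genes. For the contrast, a pseudocount of 0.1 gave 0, no filter 13, quantile normalization 4, no trend 0 and log2(CPM + 1) 0, and it could not be estimated without the methotrexate library. Adjusted over the list alone, 7 calls of drug resistance genes went to 4 with only the drug and its partners, where fewer samples enter. Here and below, drug resistance genes are counted per drug, so a gene called for several drugs counts for each. Abcb1a and Abcb1b, called for vincristine and etoposide, are such genes. The 26 calls of gene lists went to 0 with an estimated correlation and to 0 with fry. Losses and gains of transcripts, summed over derivatives, numbered 59 at 10 and 0.1 FPKM, 192 at 5 and 0.5 FPKM and 199 at 20 CPM and 3 reads, against 121.

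Leaving out each library in turn gave 0 to 9 called genes for vincristine, 0 to 5 for etoposide, 0 to 3 for prednisone, 0 to 2 for all resistant, 0 to 2 for the contrast and 0 to 3 drug resistance genes. Where this left a drug with 1 library, it was assumed to vary like the other groups. Uncalled genes changed sign. Without the replicate block Slc29a1 was at 0.12 and Bcl2l11 at -0.051. Rrm1 was at -0.047 without line 7298 and -0.018 with only its drug, and Abcb1a with prednisone at 0.0029 with only its drug. Over the libraries left out, Slc29a1 ranged from -0.12 to 0.084, Rrm1 from -0.055 to 0.22, Tubb2b from -0.75 to 0.074, Top2b from -0.39 to 0.023, Fkbp5 from -0.038 to 0.30, Bcl2l11 from -0.038 to 0.11, Il7r from -0.39 to 0.72 and Abcb1a with prednisone from -0.90 to 0.0018. Apart from fewer samples or genes in the fit, the cause was not tested. Depth limits transcripts at few reads, and depth differed between parental and resistant libraries throughout.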

Other observations

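The test of changes shared by drug was set before its result was seen; the other tests in this part were chosen after.

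Some other runs of neighbouring genes moved together, of which 3 are given here. Man2b2, Wfs1, Jakmip1 and Gm1043 (chromosome 5, 36806921 to 37229547) had a median log2 ratio of 3.66 in the cytarabine and 3.87 in the vincristine derivative of 2883. Myo7a, Capn5, Omp, B3gnt6 and Acer3 (chromosome 7, 98051060 to 98321208) were at 2.29 in the prednisone derivative of 2641 and 3.07 in the vincristine derivative of 2869. Dnmt3a, Efr3b and Dnajc27 (chromosome 12) were at -3.99 in the prednisone derivative of 2883.

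In the cytarabine derivative of 7298, Dck had neighbours at 0 reads: Grsf1 went from 1375 reads to 0 and Mob1b from 876 to 0, while Rufy3 was at a log2 ratio of -1.84 and Cox18 at -0.31. A loss of the chromosome segment may account for this. The run of 3 genes equalled the longest of 200 shuffled orders, so loss and chance cannot be told apart by run length. A scan in windows of 5 genes, with a limit of 1.72 either way on the window median, did pick out this region. Trimmed to the 4 genes from Rufy3 to Dck, the region had a median of -6.41, which is not the value held against that limit. In the cytarabine derivative of 2883 Dck was lower without its neighbours (Mob1b -0.34, Cox18 -0.32).

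The etoposide and vincristine derivatives of 2883 shared their leading V gene, Trbv12-2, and a common founder cell was tested as the reason. Their differences from the parental library correlated at r = 0.58 across genes (0.575), the highest of the pairs of 2883 derivatives. The other 9 pairs had 0.254 to 0.514. The pair at 0.514 was etoposide with cytarabine, which have different leading V genes. The shared V genes and the raised genes at Abcb1a were part of the correlation. It therefore cannot decide for or against a common founder cell. In their raised blocks at Abcb1a, Sri was higher in both (log2 ratio 5.98 and 3.10). Adam22, between Sri and Dbf4, was at 6.15 with etoposide and 0.23 with vincristine (6 to 11 reads), where the unbroken run starts at Dbf4. At the far end 9330182L06Rik was at 0.36 and 6.19. Whether the blocks arose once or separately stays open.

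Xist was lost in 4 derivatives. Reactivation of a silent X chromosome would raise X-linked genes, but in these 4 the highest median on the X chromosome minus that of autosomes was -0.065, which argues against it. Loss of the silent X chromosome was not tested.

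Derivatives resistant to the same drug in different lines had a mean correlation of differences of 0.114 (8 pairs, across genes) against 0.095 for different drugs (35 pairs). Pairs within a line had 0.387, but they share their parental library, which raises the correlation without any change. In an exact relabeling of drugs within lines, one-sided, 13 of 480 relabelings gave a mean as high (p = 0.0271). Small changes shared by drug would raise the mean in this way, but single pairs did not separate by drug. Same-drug pairs ranged from -0.10 (cytarabine in 7298 and 2883) to 0.293 (vincristine in 2696 and 2869). Different-drug pairs across lines ranged from -0.251 (cytarabine 7298 with methotrexate 2883) to 0.487 (cytarabine 7298 with vincristine 2696).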
